A study of Mus musculus and Gallus gallus with 32 samples.

How the data were processed

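Small RNA of 18 to 35 nt was sequenced from testes of mice, per the labels' protocols, with and without oxidation of the RNA, a treatment that spares RNAs carrying a 2′-O-methyl group at the 3′ end, as piRNAs do. The series held 32 samples. Of these, 30 were of mouse, 16 unoxidized and 14 oxidized, and 2 were of rooster and were not analysed here. Wild-type C57BL/6J testes were taken at 10.5, 12.5, 14.5, 17.5, 20.5 and 42.5 days post partum (dpp). A-Myb and Miwi mutants and heterozygotes were taken at 14.5 and 17.5 dpp, and Spo11 mutants and heterozygotes at 14.5 dpp and as unoxidized libraries only. Per the labels, the A-Myb and Miwi lines had a mixed 129X1/SvJ and C57BL/6J background and the Spo11 line was C57BL/6J.

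The deposited matrix gave RPKM values, in the authors' unit, for 214 piRNA loci in 40 columns, with 1 transcript per locus, and a deposited annotation gave 467 transcripts of the same 214 loci. The genome build was mm9 per the submitters' processing notes. The aligner, the counter, the treatment of reads that map to several places and the reads behind the per-million scale were not given in the sources used here. Each genotype, age and library type was 1 sample. At 14.5 dpp several columns stood for 1 sample of each library type (2 for the A-Myb heterozygote, 3 for the A-Myb mutant, 2 for each Miwi genotype). Their log2 values were averaged and counted as 1 replicate. No column was left unused. The targeted genes themselves were not among the 214 loci, so the labels could not be checked on them.

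The values carried an added 0.001 RPKM. After it was subtracted, the 60 lowest values of each column multiplied by exon length were whole multiples of a single step per column, within 0.02 of a step, in at least 98.3% of cases (4% by chance, and at most 30.0% without the subtraction). With this step taken as 1 read, the columns held 94023 to 67356430 reads on these loci. The same step put the per-million scale at 4.08 to 1432 times 1e6 reads. The step could be a fraction of a read if reads that map to several places were apportioned, and the read numbers, intervals and limits of a count of 0 given here would then not be in whole reads. Whatever the step is, what sets the scale of each column is unknown, and levels compared between libraries rest on a scale whose basis was not given in the sources used here. Ratios of loci within a library do not depend on it.

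Loci were tested with limma 3.58.1 (R 4.3.3) on log2(RPKM + 1) with a mean-variance trend and Benjamini-Hochberg adjustment, over loci with a mean of at least 1 RPKM; an adjusted p under 0.05 was a call. The pseudocount of 1 understates changes of low loci, and the fitted change of a locus without reads in a library depends on it. Genotypes were compared in an additive fit of genotype and age over the 12 unoxidized libraries at 14.5 and 17.5 dpp, with 4 residual degrees of freedom. The change of the mutant effect with age was an interaction with all non-mutant libraries as a single class (5 residual degrees of freedom). The wild-type trend was a slope on log2 of age over 6 libraries (4 residual degrees of freedom), in log2 units per doubling of age. Oxidized and unoxidized libraries were compared within 14 pairs of the same genotype and age (13 residual degrees of freedom). Locus sets were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Camera compares a set with the other loci, so its direction can differ from the sign of the set's own median. Each limma p rests on the residual of its fit over single samples. In the genotype fit this is the departure from additive effects of genotype and age, and in the trend that from a straight line. Such departures can hold real differences besides the spread between samples. Nothing in the labels gives animals per sample.

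Timing classes came from the unoxidized wild-type libraries: log2 of the mean at 17.5, 20.5 and 42.5 dpp over the mean at 10.5 and 12.5 dpp, each plus 1 RPKM. Loci at 2 or above were late-rising, loci at 0 or below early, and the others intermediate. Wilson intervals at 95% were given for single-library read shares, and 3 reads were taken as the limit of a count of 0; both cover counting error only. Since the classes rest on wild-type libraries used in the age trend, their direction in that trend is not independent. The other sets were loci of divergent pairs (5′ ends on opposite strands within 1000 bp), loci named for genes or for chromosome bands, spliced loci, and loci spanning over 20000 bp. The set of X-linked loci held 0 loci, and the table held no marker genes of other cell types. Loci named in the text were, per comparison, the 8 largest falls and the 8 largest rises past the threshold (or the 3 largest each way where none passed), the 6 highest loci in wild type at 42.5 and at 10.5 dpp, and the 3 most abundant divergent pairs at 17.5 dpp; others are said to have been chosen after their values were seen. Loci named for chromosome bands are given by chromosome and the mm9 position of their 5′ end. The limma comparisons, set tests, age correlations, sets and naming rules, and the alternatives except those named as added, were fixed before the data were examined. The change of the Miwi effect with age was not among these and was added later. The sign-flip tests over oxidation pairs and the tests of explanations in the closing section, except the exchange of libraries within pairs, were chosen after the data were seen. The alternatives were other pseudocounts, filters, centrings, variance models, control classes, age scales and library types, and each library left out in turn.

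The fits were tested on 100 simulated data sets per comparison, with the residuals of whole libraries redrawn and 60 loci changed by known amounts. The changed loci were drawn at random from all tested loci, so the called shares are not those of a timing class. In the A-Myb comparison (213 loci), 41.0% of loci changed by -2 on the log2 scale were called, 64.4% of those changed by -4 and 91.5% of those changed by -8, and 2.50% of unchanged loci were called. These falls were added without a floor, although log2(RPKM + 1) cannot lie below 0. In the unoxidized A-Myb heterozygote the early median was 1.77 at 14.5 dpp and 1.44 at 17.5 dpp on this scale. A median early locus could thus not change by -2, and these shares do not measure how well falls of early loci would be called. In the wild-type trend (213 loci), the called shares were 18.4% for a slope of -1, 53.2% for 2 and 71.0% for 4, with 2.22% of unchanged loci. In the oxidation comparison (214 loci), they were 70.2% for -0.5, 98.4% for 1 and 100% for 2, with 1.19% of unchanged loci. No unchanged locus was called in 84% of the A-Myb, 88% of the wild-type and 81% of the oxidation data sets. False calls thus fell together in the other data sets. Figures were drawn with matplotlib 3.10.9.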

Results

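The series asked how piRNA production starts during early meiosis in the mouse testis. Small RNA abundance was measured over 214 piRNA loci in 30 mouse libraries, each genotype, age and library type being 1 sample. Reads on these loci, with the smallest step of the values taken as 1 read, ranged from 94023 in the unoxidized A-Myb mutant library at 17.5 dpp to 67356430 in the oxidized A-Myb heterozygote library at 17.5 dpp. By their course in wild type, 129 loci were late-rising, 64 early and 21 intermediate. Of the late-rising loci, 97 were named for chromosome bands and 32 for genes, whereas 61 of the 64 early loci and all 21 intermediate loci were named for genes. All 30 loci of the 15 divergent pairs, whose 5′ ends lay 39 to 181 bp apart, were late-rising.

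In wild type, early loci fell with age in RPKM while late-rising loci came to make up nearly all piRNA-locus reads. The median of the early loci was 6.14 RPKM at 10.5 dpp, 6.44 at 12.5 dpp, 3.80 at 14.5 dpp, 3.75 at 17.5 dpp, 2.89 at 20.5 dpp and 1.37 at 42.5 dpp in unoxidized libraries. In oxidized libraries it was 16.9 RPKM at 10.5 dpp, 25.2 at 12.5 dpp and 1.53 at 42.5 dpp. The median of the late-rising loci was 0.148 RPKM at 10.5 dpp, 5.99 at 12.5 dpp, 3.80 at 14.5 dpp, 198 at 17.5 dpp, 116 at 20.5 dpp and 201 at 42.5 dpp in unoxidized libraries. With the step taken as 1 read, the scale was 85.1, 214 and 434 times 1e6 reads at 10.5, 12.5 and 14.5 dpp. It was 4.08, 11.7 and 10.8 times 1e6 at 17.5, 20.5 and 42.5 dpp. Between 14.5 and 17.5 dpp the median late-rising locus went from 12399 to 4943 reads and the median early locus from 9813 to 93. Whether late-rising loci rose or early loci fell at this step thus rests on the unknown scale, as do the timing classes. Late-rising loci held 22.8% of locus reads at 10.5 dpp (95% Wilson interval 22.7 to 23.0), 90.9% at 12.5 dpp (90.9 to 91.0) and 99.6% at 42.5 dpp (99.6 to 99.6); the intervals cover counting error alone. In oxidized libraries the share was lower at the early ages, 11.4% at 10.5 dpp (11.4 to 11.4) and 56.7% at 12.5 dpp (56.6 to 56.7), and 99.6% at 42.5 dpp (99.6 to 99.6). The plus-strand locus at 59106922 to 59123501 on chromosome 15 (mm9) went from 3.57 RPKM at 10.5 dpp to 12589 at 17.5 dpp, and pi-Mllt6.1 (chromosome 11, 97524531 to 97546757) from 8.53 RPKM at 10.5 dpp to 0.499 at 42.5 dpp.

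**Figure D1:**
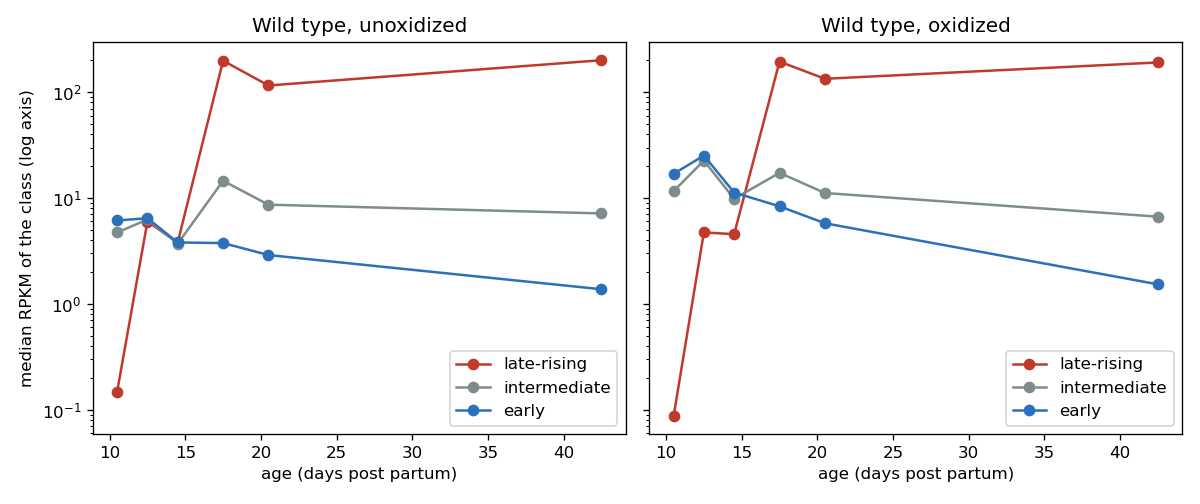
Median RPKM of late-rising, intermediate and early loci (log axis) against age in days post partum, for the 6 wild-type ages in unoxidized (left) and oxidized (right) libraries, 1 library per point. In unoxidized libraries the late-rising median lies at 0.148 RPKM at 10.5 dpp and at 201 at 42.5 dpp, and the early median at 6.14 and 1.37.

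By limma's slope on log2 age with Benjamini-Hochberg adjustment, 31 of 213 loci fell and 2 rose, and 142 had an unadjusted p under 0.05. All 31 falling loci were early (42 of the 64 adjusted over the list alone), with a median slope of -0.75 per doubling of age. Since the classes were defined on these same libraries, that the falling loci were early and the rising ones late-rising is not independent evidence. The steepest falls were at pi-Mllt6.1 (-1.35 ± 0.25, SE, limma adjusted p = 0.0188), pi-Rcan3.1 (-1.28 ± 0.24), pi-Trim71.1 (-1.25 ± 0.22), a locus named for a developmental RNA-binding protein gene, and pi-Foxo3.1 (-1.18 ± 0.23). The 2 rising loci were the chromosome 7 locus from 132493385 (2.20 ± 0.57, limma adjusted p = 0.0413) and the chromosome 3 locus from 20405121 (1.63 ± 0.41, limma adjusted p = 0.0361), the latter with a slope of -0.25 when each library was centred on all loci. The other 127 late-rising loci did not pass, although their class had a median slope of 3.44 and all 129 slopes lay above 0 (0 of 129 adjusted over the list alone; camera adjusted p = 0.0616 with an estimated correlation). The chromosome 15 locus from 59106922 had a slope of 4.30 ± 1.79 (limma adjusted p = 0.0740). Intermediate loci had a median slope of 0.24, with 0 of 20 called.

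The count of wild-type calls depended on single libraries. It was 0 without the 20.5 dpp library, 152 (38 lower, 114 higher) without the 17.5 dpp library and 142 (14 lower, 128 higher) without the 42.5 dpp library. With each library centred on the median of all loci the split was 79 lower and 56 higher, and centred on the early loci it was 1 lower and 146 higher; in oxidized libraries it was 57 lower and 86 higher. Sums of RPKM gave 8 correlations with age, over 6 libraries each. The classes were defined on the unoxidized wild-type libraries by their course with age. The direction of the class sums is thus not independent evidence, and their p-values do not allow for this. The early sum had Pearson's r = -0.79 (exact permutation p = 0.0736, adjusted 0.209) and Spearman's rho = -0.89 (exact permutation p = 0.0333, adjusted 0.133) in unoxidized libraries, and the late-rising sum r = 0.63 (exact permutation p = 0.124, adjusted 0.209) and rho = 0.77 (exact permutation p = 0.103, adjusted 0.137). Without the libraries at 42.5 and 10.5 dpp, r was -0.74 and 0.75. None of the 8 passed after adjustment.

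A-Myb (Mybl1) is a transcription factor of meiotic spermatocytes, and its mutants were compared with heterozygotes to ask which piRNA loci need it. Late-rising loci were far lower in the mutants, and early loci were not called. In unoxidized libraries the median late-rising locus stood at 24.0 RPKM in the heterozygote and 0.121 in the mutant at 14.5 dpp, and at 63.9 and 0.0141 RPKM at 17.5 dpp. The early median was 2.42 and 1.73 RPKM at 14.5 dpp and 1.71 and 1.07 at 17.5 dpp. The chromosome 15 locus from 59106922 stood at 4416 RPKM in the heterozygote at 17.5 dpp and was listed at the added value of 0.001 in the mutant, where a count of 0 allows up to 0.0498 RPKM.

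**Figure D2:**
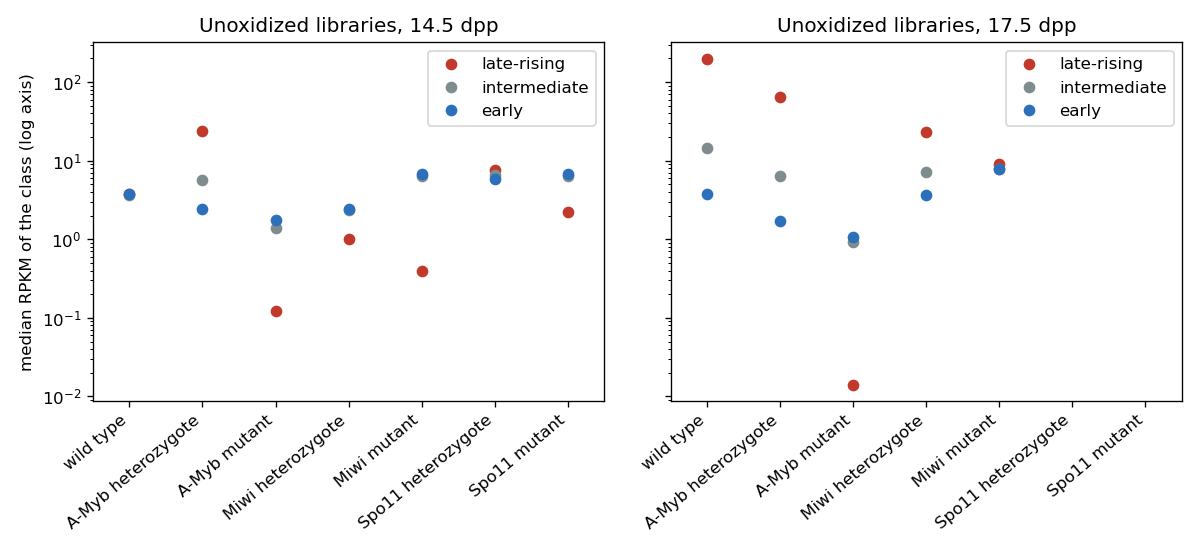
Median RPKM of late-rising, intermediate and early loci (log axis) in each unoxidized library at 14.5 dpp (left) and 17.5 dpp (right), 1 library per point; Spo11 libraries were of 14.5 dpp alone. The late-rising median of the A-Myb mutant lies at 0.121 RPKM at 14.5 dpp and 0.0141 at 17.5 dpp, below every other library of the same age.

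With limma and Benjamini-Hochberg adjustment, 113 of 213 loci fell and 0 rose (138 with an unadjusted p under 0.05). Of these, 106 were among the 128 late-rising loci tested (118 adjusted over the list alone), with a median change of -5.13, and 7 were among the 21 intermediate loci (0 adjusted over the list alone), with a median of -1.45. None of the 64 early loci was called, although 61 of them lay below 0, and their median was -0.37. The largest falls were at the chromosome 15 locus from 59106922 (-10.74 ± 2.07, SE), the chromosome 8 locus from 112641566 (-9.16 ± 1.86), the chromosome 17 locus from 27462142 (-8.97 ± 1.63) and the chromosome 8 locus from 94713359 (-8.81 ± 1.82), each with a limma adjusted p of 0.0221. Among the loci most abundant at 10.5 dpp, pi-Hist1h1a.1, named for a linker histone gene, had -1.02 ± 1.03 (limma adjusted p = 0.426) and pi-Rplp1.1, named for a ribosomal protein gene, -0.36 ± 0.69 (limma adjusted p = 0.687), or 2.81 when each library was centred on all loci.

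Of the 30 loci in divergent pairs, 29 fell (29 adjusted over the list alone), with a median of -7.14. The exception was the chromosome 7 locus from 132493385 (named after its value was seen), at -1.35, which stood at 2.87 RPKM in the heterozygote at 17.5 dpp. Where the mutant lies near 0, the size of a change in log2(RPKM + 1) follows the level in the heterozygote. At 17.5 dpp the median divergent locus stood at 224 RPKM in the heterozygote and 0.0059 in the mutant. The median late-rising locus stood at 63.9 and 0.0141. A larger change, here or among the largest falls, thus does not show a greater need for A-Myb. In the chromosome 17 pair that starts at 27462142 on the plus strand and at 27461973 on the minus strand, 169 bp apart, the changes were -8.97 ± 1.63 and -8.72 ± 1.73, and in the chromosome 7 pair that starts at 80961481 on the plus and at 80961355 on the minus strand, 126 bp apart, -8.16 ± 1.79 and -7.86 ± 1.74. Band-named loci fell in 81 of 99 cases (90 adjusted over the list alone) and gene-named loci in 32 of 114 (0 adjusted over the list alone). Spliced loci fell in 71 of 158 cases (57 adjusted over the list alone, median -1.91) and loci spanning over 20000 bp in 57 of 123 (51 adjusted over the list alone, median -2.03). Name and splicing went with timing. Of the 129 late-rising loci 97 were band-named and 77 spliced. Of the 64 early loci, none of which was called, 3 were band-named and 61 spliced. The contrasts by name and splicing thus do not stand apart from timing.

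Against the other loci, the late-rising set was lower by camera (p = 5.76e-33), but not with an estimated correlation (adjusted p = 0.226); fry gave an adjusted p of 0.0462 for a fall of the set. The early set was placed above the other loci by camera although its median change was -0.37, and not with an estimated correlation (adjusted p = 0.132); fry placed it below 0 (adjusted p = 0.16). For gene-named, spliced and long-span loci too, camera's direction was up while the median change was below 0, since camera compares a set with the other loci. The count of 113 was 0 without the A-Myb heterozygote library at 14.5 dpp, without that at 17.5 dpp or without the mutant library at 17.5 dpp, and it was 72 and 70, respectively, without the Miwi heterozygote libraries at 14.5 and 17.5 dpp. It was also 0 with a pseudocount of 10 RPKM. The median change of all loci was -2.93, and with each library centred on it the split was 70 lower and 76 higher; centred on the early loci, 103 were lower and 0 higher.

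Non-mutant libraries of the same age were themselves far apart in late-rising loci. At 14.5 dpp their medians ran from 0.994 RPKM in the Miwi heterozygote through 3.80 in wild type to 24.0 in the A-Myb heterozygote, and at 17.5 dpp from 23.4 in the Miwi heterozygote to 198 in wild type. The A-Myb effect at 17.5 dpp minus that at 14.5 dpp had a median of -3.47 over late-rising loci with all non-mutant libraries as control. Against the heterozygote of the same age alone, the late-rising median change was -4.27 at 14.5 dpp and -5.85 at 17.5 dpp. With the mutant near 0, this change grows with the heterozygote median, which was 24.0 and 63.9 RPKM at these ages. By locus, 0 of 213 passed limma's interaction test (smallest adjusted p = 0.370, 0 with an unadjusted p under 0.05).

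Miwi is a PIWI protein that binds piRNAs of meiotic and later germ cells. In its mutants late-rising loci lay below and early loci above the heterozygote, and no locus passed. The late-rising median was 23.4 RPKM in the heterozygote and 9.02 in the mutant at 17.5 dpp, and the early median 3.61 and 7.84. The median change was -0.94 for late-rising, 0.79 for intermediate and 0.98 for early loci, with 63 of 64 early loci above 0, and -1.23 for loci in divergent pairs. In oxidized libraries the early median change was smaller, 0.27 at 14.5 dpp and 0.15 at 17.5 dpp, with 7 and 18 of 64 loci below 0, while the late-rising median change was -0.10 and -1.44. With limma, 0 of 213 loci were called (smallest adjusted p = 0.276), and 37 had an unadjusted p under 0.05. The lowest values were at pi-Ip6k1.1 (-2.10 ± 0.71, limma adjusted p = 0.276), the chromosome 17 locus from 49252836 (-1.74 ± 1.63) and the chromosome 15 locus from 59106922 (-1.68 ± 2.07), the last 2 with a limma adjusted p of 0.793, and the highest at pi-Trim71.1 (1.43 ± 0.38, limma adjusted p = 0.276) and pi-Bend4.1 (1.39 ± 0.40, limma adjusted p = 0.276). pi-Ip6k1.1 was near 0 in some columns of the mutant and not in others. Camera with an estimated correlation gave an adjusted p of 0.0896 for both the late-rising and the early set.

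The difference between the A-Myb and Miwi effects had a median of -4.26 over late-rising and -1.33 over early loci. By limma, 0 of 213 loci passed (smallest adjusted p = 0.0927), and 114 had an unadjusted p under 0.05. With wild type and heterozygotes as a single control class 71 loci passed, without the wild-type library at 14.5 dpp 101, and without the A-Myb mutant library at 14.5 dpp 124, all lower in the A-Myb mutant. The change of the Miwi effect between ages passed at 0 loci (limma, smallest adjusted p = 0.997, 0 with an unadjusted p under 0.05).

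Spo11 makes the DNA double-strand breaks of meiosis, and its mutant offers a comparison with another line that is defective in meiosis. At 14.5 dpp the late-rising median was 7.54 RPKM in the Spo11 heterozygote and 2.24 in the mutant, while the early median was 5.85 and 6.87. Median changes were -1.59 for late-rising, -0.02 for intermediate, 0.16 for early and -2.88 for divergent loci, all 30 of the last below 0. The lowest values were at the chromosome 14 locus from 24901216 (-4.24 ± 2.44), the chromosome 15 locus from 59106922 (-3.98 ± 2.93) and the chromosome 9 locus from 67581593 (-3.83 ± 2.41), and the highest at pi-Rplp1.1 (1.63 ± 0.98). With 1 library of each genotype and the spread taken from the other genotypes, 0 of 213 loci passed limma's test (smallest adjusted p = 1, 0 with an unadjusted p under 0.05). The A-Myb effect minus the Spo11 effect had a median of -3.64 over late-rising loci and passed at 0 of 213 (limma, smallest adjusted p = 0.397, 0 with an unadjusted p under 0.05). Unlike ages enter this difference. The A-Myb effect was fitted over 14.5 and 17.5 dpp, the Spo11 effect at 14.5 dpp alone. Over all 129 late-rising loci, the A-Myb median change was -4.27 at 14.5 dpp and -5.85 at 17.5 dpp. The Spo11 median change over the same loci was -1.58 at 14.5 dpp. The 17.5 dpp libraries thus enlarged the difference.

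Oxidation spares RNAs protected at the 3′ end, and oxidized libraries were compared with unoxidized ones to see at which loci the values differ. The comparison cannot show which loci yield protected RNAs, since the basis of the scale is unknown. In unoxidized wild type the loci already made up 83.0%, 53.2% and 66.0% of the scale at 17.5, 20.5 and 42.5 dpp. If the scale includes these reads, late-rising loci had limited room to rise there. A locus not called is thus not shown to lack protection. All 64 early and all 21 intermediate loci were higher in oxidized libraries, while most late-rising loci were not called. The median difference was 1.54 for early, 1.28 for intermediate and 0.04 for late-rising loci. The largest rises were at the chromosome 7 locus from 82926993 (1.92 ± 0.20, SE, 14 pairs, limma adjusted p = 4.76e-07), pi-Rab11fip4.1 (1.88 ± 0.19), pi-Trim71.1 (1.87 ± 0.18) and pi-Rplp1.1 (1.87 ± 0.23). Of the 129 late-rising loci, 28 rose and 6 fell (24 and 4 adjusted over the list alone); of the 32 named for genes 22 rose and 1 fell, and of the 97 named for bands 6 rose and 5 fell. The lowest were the chromosome 17 locus from 27462142 (-0.61 ± 0.25, limma adjusted p = 0.0440) and pi-1700016M24Rik.1 (-0.53 ± 0.12, limma adjusted p = 0.000990). Of the 30 loci in divergent pairs 0 rose and 3 fell (1 adjusted over the list alone).

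**Figure D3:**
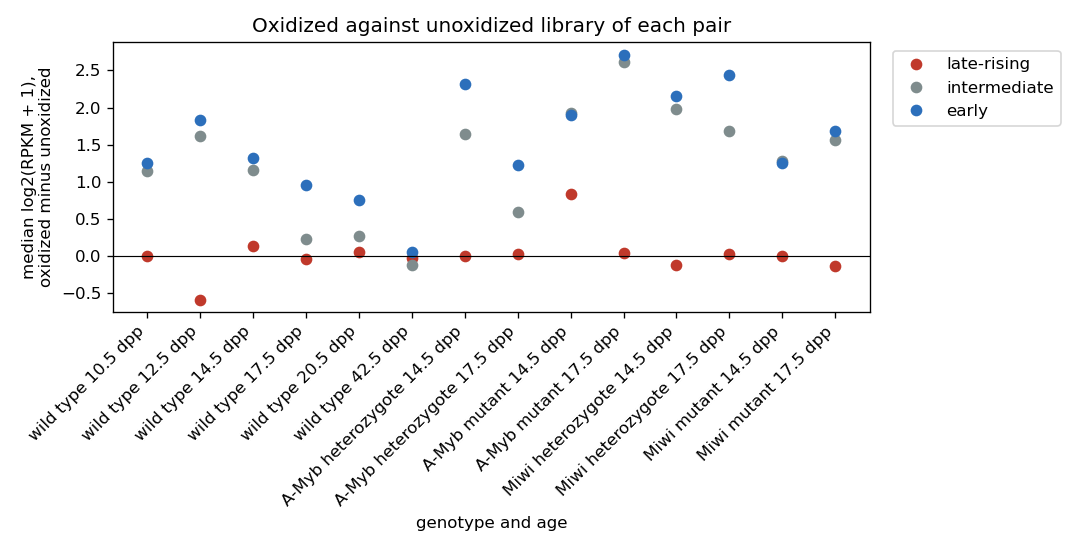
Median log2(RPKM + 1) of the oxidized minus the unoxidized library for late-rising, intermediate and early loci in each of the 14 pairs of the same genotype and age. The early minus late-rising difference lies above 0 in all 14 pairs, from 0.08 in wild type at 42.5 dpp to 2.67 in the A-Myb mutant at 17.5 dpp.

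In all, limma with Benjamini-Hochberg adjustment called 113 of 214 loci higher and 6 lower (125 with an unadjusted p under 0.05). The late-rising set lay below the other loci also with an estimated correlation (camera adjusted p = 0.00921), although its own median was 0.04 and fry's direction was up (adjusted p = 0.439), and the early set did not lie above them so (adjusted p = 0.0904). In a test chosen after this difference was seen, the early median exceeded the late-rising median within pairs, on the log2(RPKM + 1) scale, where low loci can move little, by 1.55 ± 0.77 (SD, n = 14; permutation p = 0.000122 over all 16384 sign patterns, the smallest they can give), and by 1.87 ± 0.63 (SD, n = 8) in the pairs other than wild type, all 8 above 0 (exact permutation p = 0.00781). The direction of single loci depended on the centring: centred on the median of all loci, 109 were lower and 82 higher, and centred on the early loci, 172 were lower and 10 higher. Without the A-Myb mutant pair at 14.5 dpp, 34 were lower and 112 higher.

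**Figure D4:**
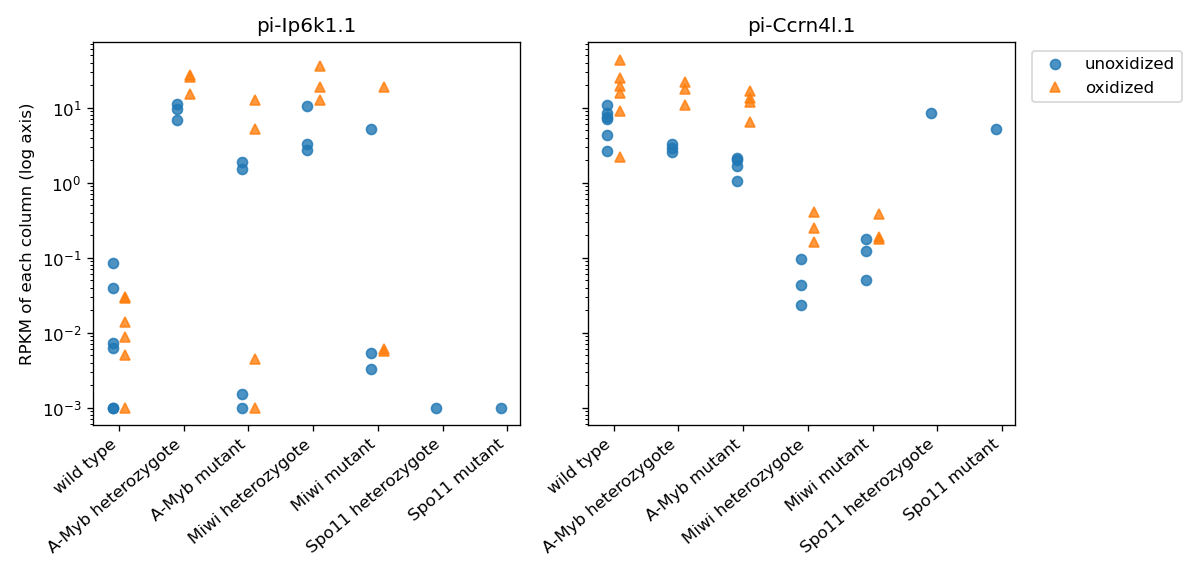
RPKM (log axis) of pi-Ip6k1.1 and pi-Ccrn4l.1 in each of the 40 columns by genotype, circles for unoxidized and triangles for oxidized columns; 0.001 stands for no reads. pi-Ip6k1.1 lies at or below 0.085 RPKM in all 14 C57BL/6J columns, and pi-Ccrn4l.1 at or below 0.402 in all 12 columns of the Miwi line.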

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

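The tests in this part were chosen after the results they measure were seen, except the count over exchanged pairs. In oxidized libraries the A-Myb mutant stood below the heterozygote at 14.5 dpp and above it at 17.5 dpp in classes other than late-rising. The 14.5 dpp values are means of columns that differed. Early medians were 12.9, 12.2 and 5.38 RPKM in the 3 mutant columns and 17.46 and 20.12 in the 2 heterozygote columns. Each mutant column thus lay below each heterozygote column at 14.5 dpp. From 14.5 to 17.5 dpp the early median went from 10.3 to 12.9 RPKM in the mutant and from 18.8 to 5.87 in the heterozygote. The change of sign thus rested mainly on the heterozygote library at 17.5 dpp. The median difference was -0.88 at 14.5 dpp and 1.01 at 17.5 dpp for early loci, with 64 of 64 loci below 0 and 64 of 64 above it, and -0.98 and 0.31 for intermediate loci. This difference between ages rests on 1 library per genotype and age and was not tested for the classes; locus by locus, limma's interaction test in oxidized libraries called 0 loci.

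The first pattern weighed was the low level of late-rising loci in A-Myb mutants. A scale factor per library leaves the ratio of late-rising to early median RPKM within a column as it is, but at both ages and in both library types this ratio was lower in each mutant column than in each heterozygote column, the highest mutant being at most 0.326 times the lowest heterozygote. Whether the mutant testis merely lacks the cells in which these loci come on cannot be told apart from a direct need for A-Myb. The ratio of late-rising to early medians in the mutant, divided by that of wild type at 10.5 dpp, was 0.544 at the lowest and 20.9 at the highest of 4 libraries, and repeat columns of a mutant sample differed up to 44.2-fold. An effect beyond that in Spo11 mutants stays open too, since the smallest adjusted p of that difference (limma) was 0.397. That difference also set A-Myb over both ages against Spo11 at 14.5 dpp alone.

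The second pattern was that early loci were higher in oxidized libraries and most late-rising loci were not called. Neither the scale nor the pseudocount accounts for the difference between the classes in the 9 pairs where most late-rising loci had a geometric mean of at least 1 RPKM. Without a pseudocount, a factor per library cancels in this difference. It averaged 1.76 ± 0.96 (SD) and was above 0 in all 9 (exact permutation p = 0.00391, the smallest the 512 sign patterns can give), though only 0.03 in wild type at 42.5 dpp. Since the factor cancels, the test cannot tell whether early loci rose or late-rising loci fell. In the 5 other pairs both the scale and the pseudocount stay open. The difference averaged 1.03 ± 1.87 (SD) over 4 pairs, as the A-Myb mutant at 17.5 dpp had only 17 such loci. Without the pseudocount and over loci of at least 1 RPKM alone, it went from 1.25 to 0.20 in wild type at 10.5 dpp (32 late-rising loci kept). At 14.5 dpp it went from 1.25 to 0.26 in the Miwi mutant (39 kept) and from 1.06 to -0.14 in the A-Myb mutant (30 kept). In the Miwi heterozygote at 14.5 dpp it went from 2.28 to 3.83 (62 kept). The pseudocount and the loci changed together, so neither can be named as the reason. A gene name is not the whole of the difference between the classes. Without a pseudocount early loci exceeded gene-named late-rising loci by 1.16 ± 0.81 (SD) over the 12 pairs with most of these at 1 RPKM or above. Of 100 ways of exchanging the libraries within pairs only the real one, counted as 1, gave as many as 119 called loci. So many calls by chance are thus unlikely, but so few ways cannot exclude it. The highest other gave 117, with only 2 pairs exchanged, and 95 others gave none. No biological explanation was tested.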

How the results depend on the processing

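Tests on each deposited column as a library and the wild-type comparison of 17.5 dpp and later with 14.5 dpp and earlier were added after seeing the data. Taking columns as libraries counts repeat columns of 1 sample as replicates. Its counts (189 for A-Myb minus Miwi) can rise for that reason alone and are not evidence of a difference. Counts of loci called by limma in the Miwi, Spo11 and A-Myb minus Spo11 comparisons and in the A-Myb interaction with age were 0 under every alternative run. For Spo11, A-Myb minus Spo11 and the interaction this says nothing about stability, since 0 loci had an unadjusted p under 0.05. Using all transcripts was not run, since the matrix holds 1 per locus. Under 17 of 23 alternatives the A-Myb count lay between 81 and 157 (in 1 of them, centred on all loci, with 76 higher), and under 17 of 23 the oxidation count lay between 91 and 124. Loci with few reads limit the A-Myb mutant at 17.5 dpp, the library with the fewest (94023). Leaving out a library can leave a genotype with 1 library, which is then assumed to vary like the others.

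The 113 A-Myb calls became 0 with a pseudocount of 10 RPKM and 146 (70 lower, 76 higher) when centred on all loci, and 0 to 141 with a library left out: 0 without either A-Myb heterozygote or without the mutant at 17.5 dpp, 72 and 70 without the Miwi heterozygotes at 14.5 and 17.5 dpp. The A-Myb minus Miwi count of 0 became 71 with pooled controls, 189 with columns as libraries and 0 to 124 with a library left out (101 without wild type at 14.5 dpp, 124 without the A-Myb mutant at 14.5 dpp). The 33 wild-type calls became 114 with a pseudocount of 10, 0 with a minimum of 10 RPKM (132 loci tested) or without the variance trend, 135 and 147 centred on all or early loci, 143 in oxidized libraries, 171 on ranks of age, 142 without 42.5 dpp, 165 in the added comparison, and 0 (without 20.5 dpp) to 152 (without 17.5 dpp) with a library left out. The 119 oxidation calls became 138 (24 lower, 114 higher) with a pseudocount of 10, 60 with a minimum of 10 RPKM (144 loci tested), 191 and 182 centred on all or early loci, 150 without both A-Myb mutant pairs, and 114 to 146 (without the A-Myb mutant pair at 14.5 dpp) with a pair left out. The median change of late-rising loci in the A-Myb mutant, -5.13, became -7.71 and -2.74 with pseudocounts of 0.1 and 10. The 10 RPKM minimum leaves fewer loci and a left-out library fewer libraries; for the other changes the cause was not tested.

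Of 2322 values of named loci under alternatives, 2040 kept direction and side of the threshold, 116 fell short of it, 111 newly passed it, 44 changed sign without a call on either side, and 11 changed sign with a call on at least 1 side, 4 of them called before. Centred on all loci, the A-Myb changes of the chromosome 1 locus from 120355843, pi-Rplp1.1, pi-Lsmd1.1 and pi-Rab11fip4.1 became 2.70, 2.81, 2.39 and 3.01, the wild-type slope of the chromosome 3 locus from 20405121 -0.25, and the oxidation difference of the chromosome 1 locus from 93302606 -0.70. Centred on early loci, oxidation differences became -1.17 at the chromosome 8 locus from 112641566, -1.55 at the chromosome 1 locus from 93302606, -0.14 at pi-Fth1.1, -0.34 at pi-Hist1h1a.1 and -0.10 at pi-Lsmd1.1. Centring moves every locus of a library alike on the log2(RPKM + 1) scale, which for low loci does not undo a scale factor.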

Other observations

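The tests in this part were chosen after the values were seen, and pi-Ip6k1.1 and pi-Ccrn4l.1 were singled out for the same reason. pi-Ip6k1.1 (chromosome 9, 107904976 to 107951111, plus strand, mm9; 6 exons) was near 0 in every C57BL/6J column, wild type and Spo11 line alike, and present in every heterozygote column of the A-Myb and Miwi lines, at 2.76 to 35.5 RPKM in 12 columns. In the mutants it was above 1 RPKM in 4 of 8 A-Myb columns and 2 of 6 Miwi columns, and at 0.00613 RPKM or lower in the others. pi-Ccrn4l.1 (chromosome 3, 51028855 to 51055547, plus strand), an early locus, was low in the whole Miwi line: 0.0231 to 0.177 RPKM in its 6 unoxidized columns against 1.07 or more in the 15 others, and 0.160 to 0.402 in its 6 oxidized columns against 2.20 or more in the 13 others. Of 214 loci, it was the only one that an 8-fold gap, relative to the median of its timing class, set apart in all columns of the Miwi line; 0 were set apart so in the A-Myb line.

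A strain variant of pi-Ip6k1.1 carried from the mixed background may account for this: the highest of the 14 C57BL/6J columns was 0.085 RPKM, and no mixed-background column lay between 0.1 and 1 RPKM. Loss of A-Myb or Miwi by itself does not explain the columns near 0, since 6 of the 14 mutant columns were above 1 RPKM. Within these lines, however, all 12 heterozygote columns were above 1 RPKM and every column near 0 was of a mutant. The columns include repeats of single samples and are not independent, and this link with genotype was not tested. The same locus was read in repeat 1 of the Miwi mutant in oxidized and in repeat 2 in unoxidized columns. The difference between these repeats over the 213 other loci correlated at r = -0.724 between unoxidized and oxidized columns, against 0.869 in the A-Myb heterozygote, 0.851 in the A-Myb mutant and 0.401 in the Miwi heterozygote (across loci, which are not independent replicates). Repeat numbers crossed between the library types may be the reason; since the repeats were averaged, no tested value depends on their numbers.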
